A study of Mus musculus with 11 samples.

How the data were processed

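Gene expression was measured in 11 samples of mouse CD4 T cells from spleen and lymph nodes, purified by positive selection and sorted on GFP. Per the labels, total RNA was labelled with biotin by the Affymetrix protocol and hybridised to 1 expression array per sample. The groups were taken from the labels: naive Foxp3-negative cells (TN, n = 3), Foxp3-positive cells (Treg, n = 5) and GFP-positive cells of mice carrying a Foxp3 null allele with GFP beside a wild-type allele (GFPKO, n = 3). The deposited values are on the log2 scale and were made by the authors with RMA, which corrects for background, normalises by quantiles and gives 1 value per probe set. Its version was not stated. The scale itself was not stated either and was read from the values, which ran from 1.54 to 14.65 with nearly the same quartiles on each array. No counts or detection calls were used here, and raw intensities were not analysed here. No pair of arrays held identical values.

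The value table held 45101 probe sets, of which 35890 were in the gene table at hand. The 64 Affymetrix control probe sets were left out, as were 932 probe sets with several gene symbols and 9211 that the gene table did not list. The 34945 probe sets with 1 symbol gave 18193 genes, each taken from its probe set with the highest mean over the 11 arrays. The values were used as deposited, with no filter on dim genes. Of the single-symbol probe sets 34741 matched the RefSeq gene table by Entrez ID. That table served for names, and no positions are given. For genes with several probe sets, called probe sets were also checked for a called change in the opposite direction. This occurred in 1 gene for Treg minus TN, 3 genes for GFPKO minus TN and 8 genes for Treg minus GFPKO, none of them named here. For the named genes, 108 called combinations of gene and contrast had another probe set with a group mean above the background of 3.99, and in 53 of them, from 31 genes, such a probe set was not called. Among genes with a value printed for such a combination these were Ahr, Bcl2l1, Bcl2l11, Bid, Birc3, Cd160, Ctse, Emp1, Hs3st3b1, Ikzf1, Ikzf4, Irf4, Maf, Prf1, Rsad2, Socs2 and Vipr1, whose values rest on the brightest probe set. Actn1, Lef1 and Rrm2 were among the 31 genes only for contrasts in which their value is not printed. A probe set called the same way can still show a smaller change than the brightest one, as given below for Il2ra and Bmp7.

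A linear model with 1 mean per group was fitted to each gene over all 11 arrays with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation and no covariates. The 3 contrasts were Treg minus TN, GFPKO minus TN and Treg minus GFPKO. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over all genes within a contrast, and a gene was called at an adjusted p under 0.05. Group values are means ± SD, and log2 fold changes are given ± SE from limma. In a test on simulated data, in which known changes were added to 100 genes per size, a log2 change of 1 was called in 91% of genes for Treg minus TN, 80% for GFPKO minus TN and 91% for Treg minus GFPKO. At a log2 change of 2 the shares were 100%, 100% and 99%. Among the genes called in these runs, 10 of 201, 12 of 192 and 14 of 204 had no change added. The simulated noise was independent between genes, with 1 spread per gene for all arrays. The real GFPKO arrays correlated less with each other than those of TN or Treg (below). These shares may therefore be too favourable for the contrasts with GFPKO.

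Before the data were examined, 22 gene lists were fixed from general knowledge of T cell biology: the Treg signature, naive T cells, early genes of T cell receptor signalling, helper cytokines, helper lineage transcription factors, Foxp3 cofactors and upstream factors, trafficking receptors, receptors of co-stimulation and co-inhibition, interleukin 2 and STAT5 signalling, TGF-beta signalling, the cell cycle, interferon-stimulated genes, cytotoxic granule and NK receptor genes, glycolysis, cholesterol and fatty acid synthesis (called lipid synthesis here), the BCL2 family and apoptosis, immediate early and heat shock genes, and markers of B cells, myeloid and dendritic cells, CD8 T cells, erythroid cells and platelets, and sex. Some genes stand in several lists. The 20 lists with at least 5 measured genes were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over lists within a contrast. Each test was repeated with an estimated correlation and with fry, which asks whether the genes of a list move on balance one way and does not compare them with other genes. Of the 60 tests 39 were called with the preset correlation, 22 with the estimated correlation and 42 with fry, and all 22 were among the 39. The main contrasts, tests and alternatives were also fixed before the data were examined.

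Genes are named by a rule fixed at the same time. Per contrast it took Foxp3, the 8 genes with the largest increase and the 8 with the largest decrease among called genes whose groups did not overlap, up to 4 genes of each list with the smallest adjusted p, and up to 5 genes per direction of each class of genes called in a pair of contrasts. Predicted loci were skipped. This named 157 genes in 282 combinations of gene and contrast, of which 232 were called. Genes given as examples of the class with GFPKO outside the range of the other groups beyond the 5 per direction, such as Il17a, Ahr, Ifit1, Tbx21 and Cxcr3, were chosen for it after their values were seen. Overlaps between contrasts were compared with independent lists of the same lengths and with 100 simulations of unchanged groups that shared the same arrays. Other splits of the arrays into groups of the same sizes were counted for each contrast.

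The alternatives were the mean of all probe sets of a gene, each probe set by itself, quantile normalization, median centring, the upper 60% of genes by mean value, a trended and robust variance, array weights, fits of only the groups compared, a block for the replicate number, Treg replicates 1 to 3 alone, an adjusted p under 0.01, a log2 fold change of at least 1, and each array left out in turn. Chosen after seeing the data were a covariate for the actin 3′ minus 5′ difference and a fit without replicate 1 of all 3 groups. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.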

Results

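Expression was measured on 11 Affymetrix arrays, each hybridised with RNA of CD4 T cells sorted from spleen and lymph nodes of mice aged 6 to 8 weeks. There were 3 groups. TN arrays (n = 3) held naive CD4 T cells without Foxp3, the transcription factor that defines regulatory T cells. Treg arrays (n = 5) held CD4 T cells positive for Foxp3. GFPKO arrays (n = 3) held GFP-positive CD4 T cells of mice with 1 wild-type Foxp3 allele and 1 null allele that drives GFP, so that GFP marks cells in which the null allele is transcribed. The series title places these cells in a study of whether Foxp3 acts on enhancers that are already present in its precursors; here the 3 groups were compared in pairs. The median log2 value per array lay between 4.07 and 4.16, and 18193 genes were tested. The number of arrays limits the precision. The labels do not say that the arrays of a group came from separate mice, so p-values measure the spread between these samples, which may be technical.

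Foxp3 was the first gene examined, as a check of the labels. Its only probe set read 3.48 ± 0.45 on the log2 scale in TN (SD, n = 3), 3.47 ± 0.16 in Treg (n = 5) and 6.93 ± 0.23 in GFPKO (n = 3). The probe set read higher in GFPKO than in Treg (log2 fold change of Treg minus GFPKO -3.46 ± 0.18 SE, adjusted p = 1.4e-08), while Treg and TN did not differ by the test (log2 fold change -0.01 ± 0.18, adjusted p = 0.985). The level of 3.99, the highest Foxp3 value in TN and above the Y-linked genes in GFPKO, was taken as background after the values were seen. Where the lower group of a difference has a mean at or below it, as for Foxp3 in Treg, the difference is a lower bound and its rank among the others is not resolved. The low Treg value goes against the label, so "Treg" here means the arrays labelled Treg, and each direction given for them rests on that label. The place of the probe set in the transcript, relative to the altered part of either allele, was not known, so the value cannot be read as the amount of Foxp3 RNA or of functional Foxp3. For Foxp3 the lower bound thus holds for the signal of this probe set only. Xist, the RNA made from the inactive X chromosome of females, read 11.34 ± 0.44 in GFPKO, against 3.78 ± 0.06 in TN and 3.67 ± 0.21 in Treg. The Y-linked genes Eif2s3y, Kdm5d and Uty were lower in each GFPKO array than in any TN or Treg array, and their GFPKO values lay between 1.76 and 3.38. Every GFPKO array thus showed a female pattern and every TN and Treg array a male one, so sex and genotype could not be separated in any comparison with GFPKO.

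**Figure D1:**
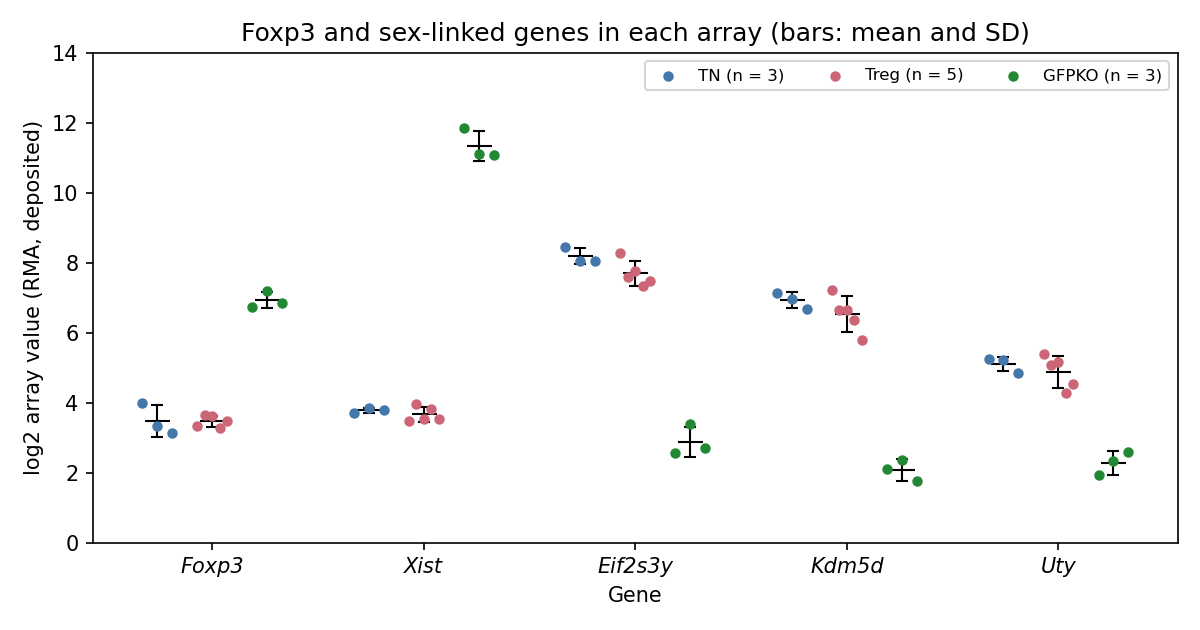
Deposited log2 values (y axis) of Foxp3, Xist and the Y-linked genes Eif2s3y, Kdm5d and Uty (x axis) in each array of TN (n = 3), Treg (n = 5) and GFPKO (n = 3); points are arrays and bars the mean and SD. Foxp3 lies between 6.75 and 7.19 in GFPKO and at most at 3.99 in the other arrays.

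The first principal component held 40.3% of the variance between arrays and separated TN from Treg. The second held 24.4% and spread the GFPKO arrays out, with replicate 1 at its end (-48.2), replicate 2 at -25.0 and replicate 3 at -1.04. The highest correlation of GFPKO replicate 3 with an array of another group was 0.988, above its mean with the other GFPKO arrays (0.984). Correlations across genes within a group were at least 0.994 in TN and 0.990 in Treg, but between 0.979 and 0.990 in GFPKO. The signal of the actin control at its 3′ end minus that at its 5′ end, a measure of RNA integrity, was 0.68 ± 0.20 in GFPKO against 0.48 ± 0.08 in TN and 0.53 ± 0.07 in Treg. The GFPKO group thus had the lowest correlations of the 3, and its actin values in replicates 1 and 2 (0.770 and 0.832) lay above those of every TN and Treg array (at most 0.611), while replicate 3 (0.451) lay among them.

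Treg and TN differed in the genes that mark regulatory T cells. Il2ra, the alpha chain of the interleukin 2 receptor, was at least 49.2-fold higher in Treg by its brightest probe set (log2 fold change 5.62 ± 0.15 SE, adjusted p = 9.3e-12). Another Il2ra probe set, also called, gave a smaller log2 fold change of 3.50, so the size depends on the probe set. Ctla4, an inhibitory receptor, was 20.4-fold higher (4.35 ± 0.17). Itgae, an integrin that binds E-cadherin, rose by 4.83, Penk, which encodes the opioid precursor proenkephalin, by 4.52, and Klrg1, an inhibitory lectin-like receptor, by 4.47 on the log2 scale. Rgs1, a regulator of G protein signalling, and Gsta4, a glutathione transferase, were higher by 4.46 and 4.36. In the other direction Pdlim4 was at least 82.6-fold lower in Treg (-6.37 ± 0.16, adjusted p = 3.5e-12). Also lower were Klrd1, an NK cell receptor chain (-5.68), Pde3b, a cyclic nucleotide phosphodiesterase (-4.90), Lypd6b (-4.31), the heparan sulfate enzyme gene Hs3st3b1 (-3.79) and Vipr1, a receptor for vasoactive intestinal peptide (-3.77). The MHC class II genes H2-Aa (-4.37) and H2-Ab1 (-4.18) were also lower in Treg. H2-Aa read 10.13 to 11.02 in the TN arrays, where several myeloid and dendritic markers were higher too (below). Whether the TN arrays held RNA of other cells was not tested, so these values cannot be read as a change within CD4 T cells. Lower bounds in this comparison, because TN was at background, are the values of Il2ra, Il10, Itgb8 and Kif20a, and, because Treg was, those of Pdlim4, Klrd1, Hs3st3b1, Gzmk, Il2, Ly86 and Siglech. In all 1813 of 18193 genes were called at an adjusted p under 0.05 in limma, 1190 higher and 623 lower in Treg, and 496 and 211 of these by at least 2-fold. The lower count was 411 without TN replicate 1 and 388 without TN replicate 2. A fit of only Treg and TN called 2551 genes.

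All 28 measured genes of the Treg signature list were higher in Treg, with a median log2 fold change of 2.95 (camera adjusted p = 1.1e-59). The same 28 were called when adjusted over the list alone. Tnfrsf4 (4.17), a co-stimulatory receptor of the TNF receptor family, was among them. Of 19 receptors of co-stimulation and co-inhibition, 13 rose and 1 fell (15 and 2 adjusted over the list alone), including Tnfrsf9 (2.88) and Tnfrsf18 (2.15). Of 13 genes of interleukin 2 and STAT5 signalling, 8 rose and none fell in limma (12 and 1 adjusted over the list alone), among them Socs2 (4.74), the feedback inhibitor gene Cish (3.39) and Il2rb (3.71). The 13 measured genes of the naive T cell list went the other way, with 8 called lower and none higher (12 lower adjusted over the list alone). Dapl1 fell by 3.53, Pde3b by 4.90, Actn1 by 1.36 and Lef1, a transcription factor of naive T cells, by 1.28. The camera adjusted p was 1.3e-17 for the receptors, 1.5e-12 for interleukin 2 signalling and 3.9e-19 for the naive list, and each held with an estimated correlation (adjusted p = 0.0017, 0.0017 and 0.00030).

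**Figure D2:**
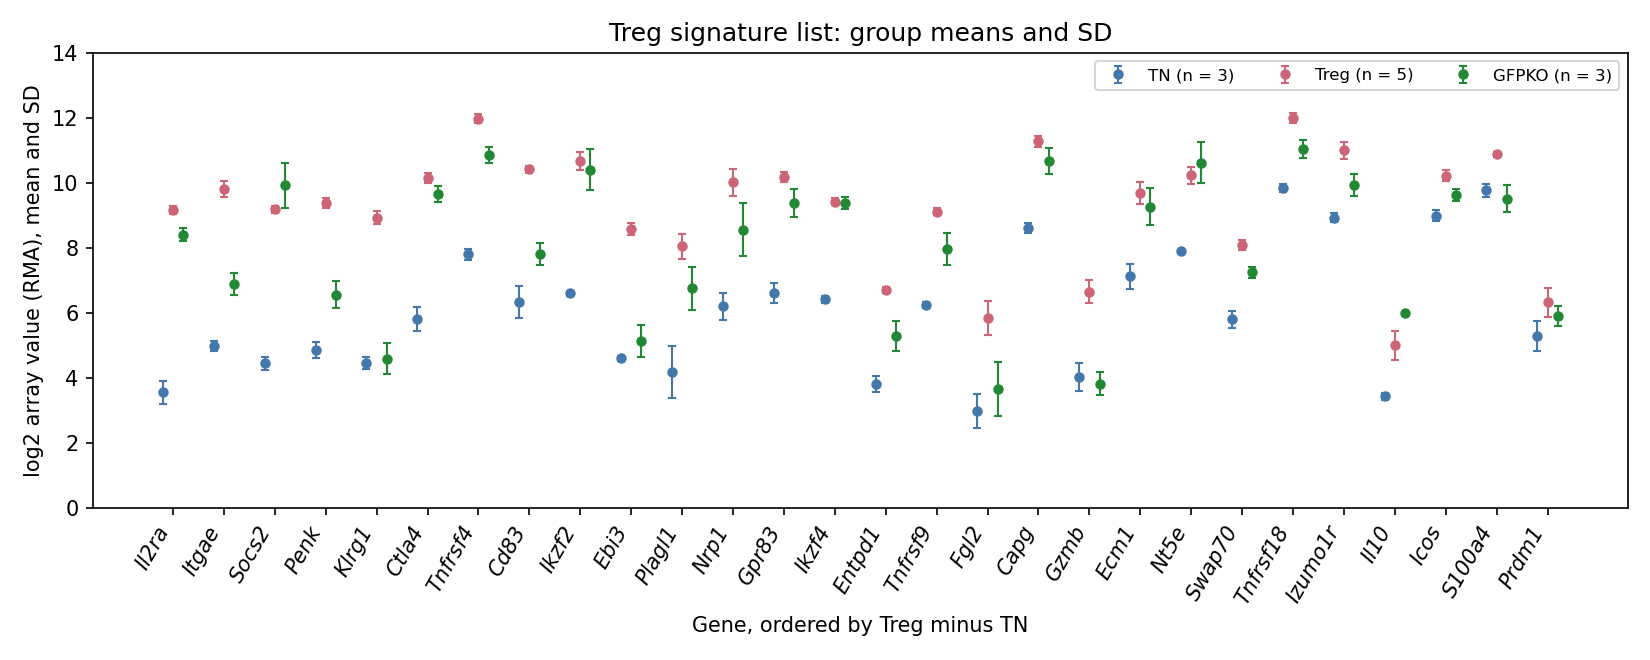
Mean log2 value and SD (y axis) of the 28 measured Treg signature genes (x axis, ordered by Treg minus TN) in TN (n = 3), Treg (n = 5) and GFPKO (n = 3). Treg lies above TN for each gene, and GFPKO lies near Treg for Ctla4 and Ikzf4 and near TN for Klrg1 and Gzmb.

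Genes induced by T cell receptor signalling were higher in Treg for 10 of 16 (11 adjusted over the list alone, camera adjusted p = 9.8e-11), among them Bhlhe40 (2.56), Irf4 (2.17), Egr2 (1.28) and Nr4a1 (1.19). Of 29 cell cycle genes 18 rose and none fell in limma (21 adjusted over the list alone, camera adjusted p = 2.6e-15), such as Rrm2 (2.12), Kif20a (1.91) and Ccnb2 (1.91). Among 12 genes of the BCL2 family and apoptosis 4 rose (6 adjusted over the list alone, camera adjusted p = 1.5e-05), among them Bid (1.02), Bcl2l1 (1.24) and Pmaip1 (1.22). The trafficking receptors held 9 higher and 3 lower genes of 23 (12 and 4 adjusted over the list alone, camera adjusted p = 0.0012), among them Itgae, Ccr6 (2.83), Itgb8 (2.66) and Gpr15 (2.61). These 4 list calls held with an estimated correlation, at adjusted p = 0.012 for the T cell receptor genes, 0.017 for the cell cycle, 0.0055 for apoptosis and 0.034 for trafficking. Helper lineage factors were called up as a list, with 8 higher and 3 lower of 17 (the same 8 and 3 adjusted over the list alone, camera adjusted p = 0.0078, but adjusted p = 0.16 with an estimated correlation): Hopx (2.85) and Ahr (2.28) rose, and Id2 fell by 1.47. The glycolysis list had 3 higher of 12 (3 adjusted over the list alone, camera adjusted p = 0.023, and adjusted p = 0.58 with an estimated correlation), which were the glucose transporter gene Slc2a3 (1.46), Hk2 (1.47) and Tpi1 (0.87).

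Markers of other cells were tested as lists. A list lower in Treg may reflect the sorted CD4 T cells or other cells in the TN arrays, which was not tested. Of 15 myeloid and dendritic markers 5 were lower and 1 was higher in Treg (6 and 1 adjusted over the list alone, camera adjusted p = 0.00046, and adjusted p = 0.16 with an estimated correlation), with Tyrobp lower by 3.31, Ly86 by 1.90, Siglech by 1.35 and Fcer1g by 1.23. Cytotoxic and NK receptor genes were lower in 6 and higher in 3 of 14 (7 and 4 adjusted over the list alone, camera adjusted p = 0.0045, and adjusted p = 0.16 with an estimated correlation): Klrd1, Prf1 (-2.21) and Gzmk (-2.06) fell, and Klrg1 rose. The other lists were not called by camera in this comparison. They had 3 higher and 3 lower of 14 helper cytokines (4 and 3 adjusted over the list alone, camera adjusted p = 0.82). The next counts are in the same order: 5 and 1 of 21 Foxp3 cofactors and upstream factors (6 and 2, adjusted p = 0.55), and 3 and 3 of 14 genes of TGF-beta signalling (6 and 4, adjusted p = 0.90). There were 4 and 1 of 19 interferon-stimulated genes (5 and 1, adjusted p = 0.23) and 2 and 0 of 17 genes of lipid synthesis (2 and 0, adjusted p = 0.26). There were also 1 and 0 of 13 immediate early and heat shock genes (2 and 0, adjusted p = 0.91), 2 and 3 of 11 B cell markers (2 and 4, adjusted p = 0.49) and 0 and 0 of 7 erythroid and platelet markers (0 and 0, adjusted p = 0.82). The B cell list had a median of -0.07 and a mean of 0.14, with Cd79b higher by 3.27. Single genes of these lists included Il10 (1.57), Lta (1.84), Il2 (-1.43), Ikzf1 (-1.10), Tgfbr3 (-3.05), Isg20 (1.01), Mx1 (0.90) and Dusp1 (2.01), all called. Neither CD8 marker was called over all genes, Cd8a at 0.34 and Cd8b1 at -0.38 (adjusted p = 0.073). Adjusted over the list alone Cd8b1 was called lower, and without GFPKO replicate 3 it was called over all genes (adjusted p = 0.029). None of the 4 sex-linked genes measured was called in limma (0 adjusted over the list alone), except Eif2s3y without Treg replicate 1 (adjusted p = 0.047). At an unadjusted p under 0.05, 1 sex-linked gene and 1 CD8 marker were lower in Treg and 0 erythroid and platelet markers passed.

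GFPKO and TN differed in many of the same genes. Socs2 was 44.6-fold higher in GFPKO than in TN (log2 fold change 5.48 ± 0.25 SE, adjusted p = 2.5e-09) and Il2ra at least 28.8-fold by its brightest probe set (4.85 ± 0.17, adjusted p = 2.6e-10). Another Il2ra probe set, also called, gave 2.58. Prg4 (4.34), Rgs1 (4.28), Gsta4 (4.23), Coro2a (4.12), the chemokine gene Ccl20 (4.07 ± 0.13) and Xist (7.56) were also higher. Lower in GFPKO were Eif2s3y (-5.31) and Kdm5d (-4.85) of the Y chromosome. So were the MHC class II genes H2-Aa (-5.23), H2-Eb1 (-4.60) and H2-Ab1 (-4.48), Klrd1 (-4.87), the chemokine gene Ccl5 (-4.11) and Hs3st3b1 (-3.82). Several myeloid markers were lower too (below), and whether the TN arrays held RNA of other cells was not tested. Lower bounds in this comparison, because TN was at background, are the values of Il2ra, Ccl20, Xist and Il10, and, because GFPKO was, those of Eif2s3y, Kdm5d, Klrd1, Hs3st3b1 and Gzmk. In limma 1029 genes were called, 480 higher and 549 lower in GFPKO, 269 and 168 of them by at least 2-fold. The balance turned with single arrays, from 373 higher and 271 lower without TN replicate 1 (644 in all) to 644 higher and 1224 lower without GFPKO replicate 3 (1868 in all). The lower count was 312 without TN replicate 2 and 362 without GFPKO replicate 2, and with the actin 3′ minus 5′ difference as a covariate, an alternative chosen after seeing the data, there were 341 higher and 229 lower (570 in all). A fit of only GFPKO and TN called 562 genes. The main fit takes 1 spread per gene over all 3 groups, so p-values can be too small for genes that vary more in GFPKO. Whether unequal spread or the fewer arrays lowered the count was not tested.

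Of the 28 Treg signature genes 22 were higher in GFPKO than in TN and none was called lower (24 adjusted over the list alone, median log2 fold change 1.82, camera adjusted p = 4.2e-47, and adjusted p = 8.9e-05 with an estimated correlation). Ctla4 rose by 3.86 and Ikzf4, a zinc finger transcription factor, by 2.96. Receptors of co-stimulation and co-inhibition were higher in 11 of 19 (12 adjusted over the list alone, camera adjusted p = 8.2e-20), with Tnfrsf4 (3.06), Lag3 (3.27) and Cd200 (1.57). Interleukin 2 and STAT5 genes were higher in 5 of 13 (8 adjusted over the list alone, camera adjusted p = 2.1e-15), Cish by 2.79 and Il2rb by 2.45. Of 19 interferon-stimulated genes 12 rose and none fell in limma (15 adjusted over the list alone, camera adjusted p = 7.1e-19): Mx1 by 2.16, Ifit3 by 1.78, Rsad2 by 1.67 and Usp18 by 1.33. With an estimated correlation the adjusted p was 0.0013 for both receptor and interleukin 2 lists and 0.013 for the interferon list. Helper cytokines were higher in 5 and lower in 1 of 14 (6 and 1 adjusted over the list alone, camera adjusted p = 0.00013, and adjusted p = 0.012 with an estimated correlation), with Il17a (2.46), the cytokine of Th17 cells, and Il10 (2.57) among the higher ones. Helper lineage factors rose in 4 and fell in 3 of 17 (6 and 3 adjusted over the list alone, camera adjusted p = 0.00013, and adjusted p = 0.044 with an estimated correlation), with Ahr (3.77), Maf (2.90), Irf4 (2.28) and Hopx (1.97) higher.

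Other lists were called up in GFPKO. T cell receptor genes were higher in 5 of 16 (8 adjusted over the list alone, camera adjusted p = 4.2e-09, estimated-correlation adjusted p = 0.015), Bhlhe40 by 1.82 and Egr2 by 0.95. Trafficking receptors had 6 higher and 2 lower of 23 (11 and 2, adjusted p = 0.00061, and adjusted p = 0.028 with an estimated correlation), with Ccr6 (2.95) and Gpr15 (1.80) higher and Cxcr3, a receptor of Th1 cells, lower by 1.58. The apoptosis list had 4 higher of 12 (6 higher and 1 lower adjusted over the list alone, adjusted p = 0.00015, and adjusted p = 0.012 with an estimated correlation), among them Bcl2l11 (1.13) and Birc3 (0.68), each with another probe set that was not called. Of the 21 Foxp3 cofactors and upstream factors only Nr4a1 (0.83) was called, yet the list was called as a whole (4 adjusted over the list alone, adjusted p = 4.3e-05, and adjusted p = 0.045 with an estimated correlation). TGF-beta signalling (4 higher and 1 lower of 14; 6 and 1 adjusted over the list alone, adjusted p = 0.0021) and the cell cycle (5 higher of 29; 7 adjusted over the list alone, adjusted p = 1.2e-07) were called, but at adjusted p = 0.085 and 0.056 with an estimated correlation. Mki67, a marker of proliferation, rose by 1.67.

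Naive T cell genes were lower in 5 and higher in none of 13 in limma (7 lower and 2 higher adjusted over the list alone, camera adjusted p = 0.0016, and adjusted p = 0.035 with an estimated correlation), Dapl1 by 2.28 and Il7r by 1.62. Cytotoxic and NK receptor genes were lower in 7 of 14 (9 adjusted over the list alone, adjusted p = 8.0e-10, and adjusted p = 0.012 with an estimated correlation), with Prf1 at -2.60 and Gzmk at -2.34. The B cell list (1 higher and 4 lower of 11, the same adjusted over the list alone, adjusted p = 0.0017) and the myeloid list (5 lower of 15, 6 adjusted over the list alone, adjusted p = 4.3e-05) were called down, with adjusted p = 0.089 and 0.079 with an estimated correlation. Cd74, the invariant chain of MHC class II, fell by 2.74 and Tyrobp by 3.29. For these lists, too, other cells in the TN arrays were not tested. Glycolysis was not called as a list (0 of 12 genes called, 0 adjusted over the list alone, adjusted p = 0.47; Slc2a3 at -0.44). The same held for lipid synthesis (0 of 17 and 0, adjusted p = 0.22, but 0.035 without TN replicate 1; Scd2 at 0.35). Immediate early and heat shock genes (1 higher and 2 lower of 13, 2 and 3 adjusted over the list alone, adjusted p = 0.32) and erythroid and platelet markers (0 of 7 and 0, adjusted p = 0.71) were not called either. At an unadjusted p under 0.05 in limma, 1 glycolysis gene was higher and 2 were lower, 1 lipid synthesis gene was higher and 0 erythroid and platelet markers passed. Cd8b1 read -0.62 against TN (adjusted p = 0.014, also called adjusted over the list alone), a call that was lost without TN replicate 1, TN replicate 2 or GFPKO replicate 2 (adjusted p = 0.069, 0.072 and 0.075). Cd8a was not called, and all 4 sex-linked genes were (1 higher and 3 lower, the same adjusted over the list alone).

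Treg and GFPKO were compared directly to ask which differences go with the allele that the cells transcribe. Apart from Xist (-7.68), Eif2s3y (4.81) and Kdm5d (4.46), genes increased in Treg were Klrg1, 20.2-fold (log2 fold change 4.34 ± 0.18 SE, adjusted p = 2.2e-09), Ccl5, 12.8-fold (3.68 ± 0.20), Ebi3, a subunit of the cytokines interleukin 27 and 35 (3.44 ± 0.18), Bmp7 (3.04), Itgae (2.92) and Gpr34 (2.85). Other Bmp7 probe sets, also called, gave 2.14 and 0.95. Increased in GFPKO were Pde3b (-4.04), the aspartic protease gene Ctse (-3.96), the signal of the Foxp3 probe set (-3.46), Plac8 (-3.43), Ccl20 (-3.38), Emp1 (-3.34) and Pdlim4 (-3.16). Lower bounds in this comparison, because Treg was at background, are the values of Xist, Foxp3, Pdlim4, Il21 and Il4, and, because GFPKO was, those of Eif2s3y, Kdm5d, Gpr34, Gzmb and Itgb8. In limma 1716 genes were called, 1252 higher and 464 lower in Treg, 263 and 138 of them by at least 2-fold. The count moved with single GFPKO arrays, to 782 higher and 352 lower without GFPKO replicate 1 (1134 in all), 870 and 282 without GFPKO replicate 2, and 2414 and 1007 without GFPKO replicate 3 (3421 in all). With each probe set by itself 1862 were higher and 2129 lower in Treg, and with the actin 3′ minus 5′ difference as a covariate, chosen after seeing the data, the genes called were 811. A fit of only Treg and GFPKO called 1341 genes, and the limit of a spread shared by all groups holds here too.

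The Treg signature was higher in Treg for 20 of 28 genes and lower for 1 (21 and 2 adjusted over the list alone, median log2 fold change 1.01, camera adjusted p = 4.7e-16, and adjusted p = 0.0025 with an estimated correlation). Penk was higher by 2.81, and the 1 gene lower in Treg was Il10 (adjusted p = 0.0054). Naive T cell genes were lower in Treg for 10 of 13 (12 adjusted over the list alone, adjusted p = 2.2e-19, and adjusted p = 0.00054 with an estimated correlation), with Dapl1 at -1.25, Satb1 at -1.01 and Lef1 at -0.79. These 2 were the only lists called in this comparison whose call held with an estimated correlation. Interferon-stimulated genes were lower in Treg for 11 and higher for 1 of 19 (12 and 1 adjusted over the list alone, adjusted p = 2.6e-14, and adjusted p = 0.050 with an estimated correlation), Ifit1 by -2.00, Ifit3 by -1.89, Rsad2 by -1.71 and Mx1 by -1.26. Helper cytokines were lower for 5 of 14 (3 higher and 5 lower adjusted over the list alone, adjusted p = 0.0034, and adjusted p = 0.050 with an estimated correlation), with Il17a at -2.63, Il21 at -2.04 and Il4 at -1.50.

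Of the cell cycle list 10 of 29 genes were higher in Treg (11 adjusted over the list alone, adjusted p = 4.6e-06), Ccnb2 by 1.47, Kif20a by 1.19, Birc5 by 1.51 and Cdk1 by 1.11. B cell markers were higher for 5 of 11 (6 adjusted over the list alone, adjusted p = 0.0011), with Cd74 at 1.85, Cd79b at 1.61, Bank1 at 1.26 and Cd22 at 0.94. With an estimated correlation the adjusted p was 0.18 for the cell cycle list and 0.18 for the B cell list. Glycolysis genes were higher for 4 of 12 (5 adjusted over the list alone, adjusted p = 0.0044, and adjusted p = 0.43 with an estimated correlation), Slc2a3 by 1.89. Foxp3 cofactors were lower for 4 of 21 (7 lower and 1 higher adjusted over the list alone, adjusted p = 0.0051, and adjusted p = 0.19 with an estimated correlation), Foxp1 by -1.10. TGF-beta signalling had 2 higher and 3 lower of 14 (2 and 6 adjusted over the list alone, adjusted p = 0.0052, and adjusted p = 0.19 with an estimated correlation), with Tgfbr3 at -2.01 and Itgb8 at 2.02. Receptors of co-stimulation and co-inhibition had 7 higher and 2 lower of 19 (9 and 2, adjusted p = 0.0073, and adjusted p = 0.19 with an estimated correlation), with Cd160 at 1.06 and Lag3 at -1.69. Cytotoxic and NK receptor genes had 5 higher and 2 lower of 14 (6 and 3, adjusted p = 0.013, and adjusted p = 0.24 with an estimated correlation), with Gzmb, granzyme B, at 2.83 and Nkg7 at 1.59. Without GFPKO replicate 3 the last 2 lists were no longer called (adjusted p = 0.072 for each), and without GFPKO replicate 1 glycolysis was not (adjusted p = 0.084).

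The T cell receptor genes were not called as a list between Treg and GFPKO (3 higher of 16, 5 adjusted over the list alone, adjusted p = 0.11; Batf at 1.11), but were called without GFPKO replicate 2 or Treg replicate 5 (adjusted p = 0.020 and 0.034). Nor were the helper lineage factors (3 higher and 3 lower of 17, the same adjusted over the list alone, adjusted p = 0.57; Tbx21 at 1.67 and Id2 at -1.51) or the trafficking receptors (6 and 5 of 23, 7 and 6 adjusted over the list alone, adjusted p = 0.86; Cxcr5 at 2.47 and Cxcr3 at 2.45). Interleukin 2 signalling had 5 higher of 13 (5 higher and 3 lower adjusted over the list alone, adjusted p = 0.25; Pim1 at 1.13). The median and mean of the helper lineage factors were 0.04 and -0.01, and those of the trafficking receptors -0.01 and 0.28. The apoptosis list (4 higher and 1 lower of 12, 4 and 3 adjusted over the list alone, adjusted p = 0.71; Bid at 1.07) and the immediate early and heat shock genes (2 and 1 of 13, 4 and 1, adjusted p = 0.14) were not called. The lipid synthesis genes (0 of 17 and 0, adjusted p = 0.88), the myeloid markers (0 of 15 and 0, adjusted p = 0.54) and the erythroid and platelet markers (0 of 7 and 0, adjusted p = 0.58) were not called either. At an unadjusted p under 0.05 in limma, 4 lipid synthesis genes were higher and 1 was lower in Treg, while 3 myeloid markers, 1 erythroid or platelet marker and 0 CD8 markers were higher. Neither CD8 marker was called (0 adjusted over the list alone), except Cd8b1 without GFPKO replicate 3 (adjusted p = 0.046). All 4 sex-linked genes were called, 3 higher and 1 lower in Treg (the same adjusted over the list alone).

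Of the 1190 genes higher in Treg than in TN, 356 were also higher in GFPKO than in TN, and 625 were also higher in Treg than in GFPKO. Coro2a was higher than in TN by 4.32 in Treg and by 4.12 in GFPKO on the log2 scale, whereas Itgae stood at 9.82 in Treg against 6.89 in GFPKO and 4.98 in TN. Of the 623 genes lower in Treg than in TN, 276 were also lower in GFPKO and 177 were lower in Treg than in GFPKO, such as Tdrp, Sgk1 and Tgfbr3 (log2 fold changes of Treg minus GFPKO -2.35, -2.18 and -2.01). Over the 1190 genes the median log2 fold change was 0.90 in Treg minus TN and 0.36 in GFPKO minus TN, and over the 623 genes it was -0.79 and -0.54. Independent lists of the same lengths would share 31.4 and 18.8 genes for the comparisons with TN, and 81.9 and 15.9 for those with Treg. In 100 simulations of unchanged groups at most 1 gene was shared, but such groups give almost no calls, so this does not measure how much of the overlap among changed genes comes from the shared arrays. Across genes, which are not independent replicates, the fold changes of Treg minus TN and GFPKO minus TN had r = 0.63 against 0.56 in the simulations, and a covariance of 0.117 against 0.0161. For Treg minus TN and Treg minus GFPKO r was 0.55 against 0.38, with a covariance of 0.0949 against 0.00971. With the Treg arrays split into 2 and 3, one part for each contrast, that r had a median of 0.49 (0.41 to 0.55 over the splits). TN and GFPKO arrays were not split in this way, so part of the excess in the overlaps that share them may come from the shared arrays.

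**Figure D3:**
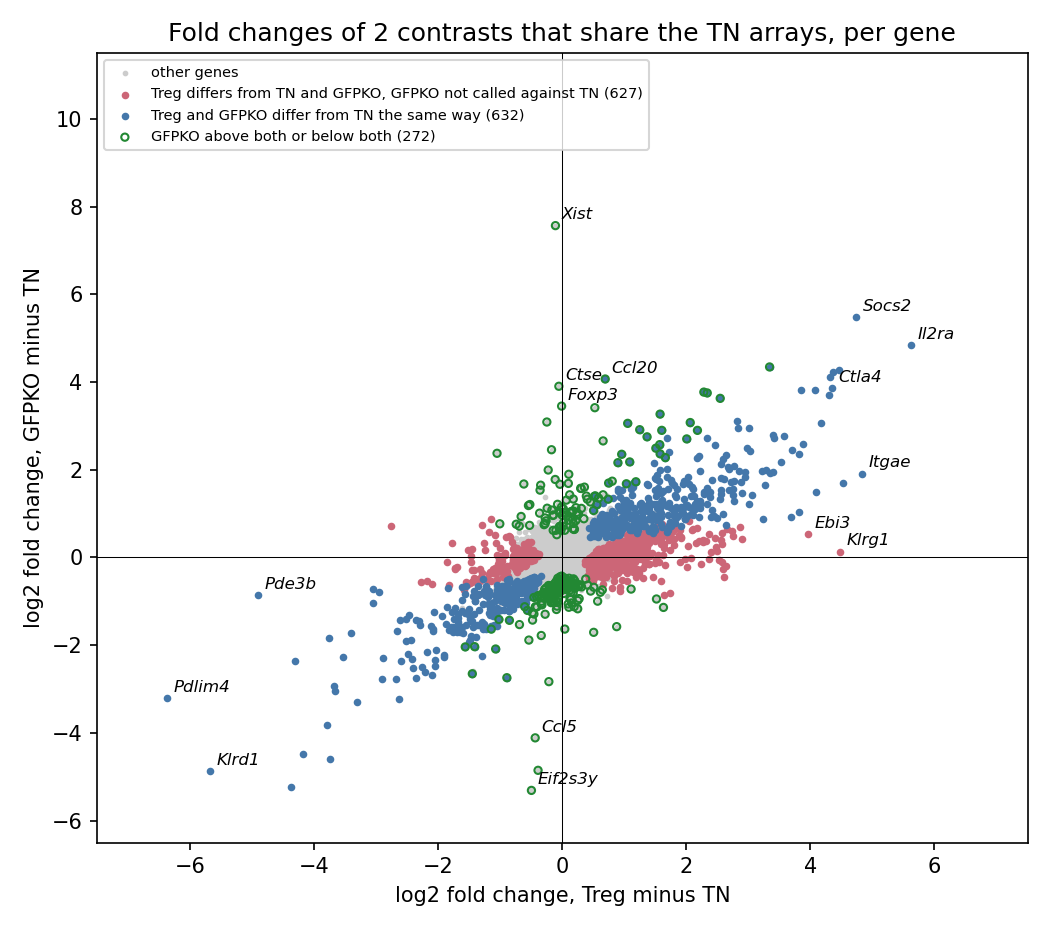
Log2 fold change of Treg minus TN (x axis) and of GFPKO minus TN (y axis) for each of the 18193 genes. Blue points are the 632 genes called the same way in both contrasts, red points the 627 genes that set Treg apart from TN and GFPKO without a call for GFPKO against TN, and green circles the 272 genes with GFPKO above both or below both.

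GFPKO did not lie only between the other groups. In 107 genes GFPKO was higher than both TN and Treg, and in 165 it was lower than both. Independent lists of the same lengths would share 12.2 and 37.8 genes. Both comparisons use the same GFPKO arrays, so part of the excess may come from these arrays. Across genes the fold changes of GFPKO minus TN and Treg minus GFPKO had r = -0.29 against -0.56 in the simulations. Their covariance was -0.0433 against -0.0162. Ctse was 15.5-fold higher in GFPKO than in Treg, with 8.10 ± 0.16 in TN (SD, n = 3) and 8.04 ± 0.30 in Treg (n = 5). Ccl20 read 7.66 ± 0.16 in GFPKO against 3.59 ± 0.11 in TN and 4.28 ± 0.10 in Treg, and Emp1 7.56 ± 0.44 against 4.48 ± 0.23 and 4.23 ± 0.23. Il17a (log2 fold change 2.46 over TN and -2.63 for Treg minus GFPKO), Ahr, Lag3, Il10, Ifit1, Ifit3, Rsad2 and Mx1 were also in this class. Dimmer probe sets of Ctse, Emp1, Ahr and Rsad2 were not called in 1 or both comparisons. Below both were the 3 Y-linked genes, Ccl5 (5.25 ± 0.61 in GFPKO, 9.36 ± 0.06 in TN and 8.92 ± 0.13 in Treg) and Cd74, as well as Tbx21, the lineage factor of Th1 cells, and Cxcr3. The number of genes of GFPKO outside the TN to Treg range, 272 in all, rested on single arrays. It was 163 without TN replicate 1, 171 without TN replicate 2, 178 without GFPKO replicate 2 and 941 without GFPKO replicate 3.

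**Figure D4:**
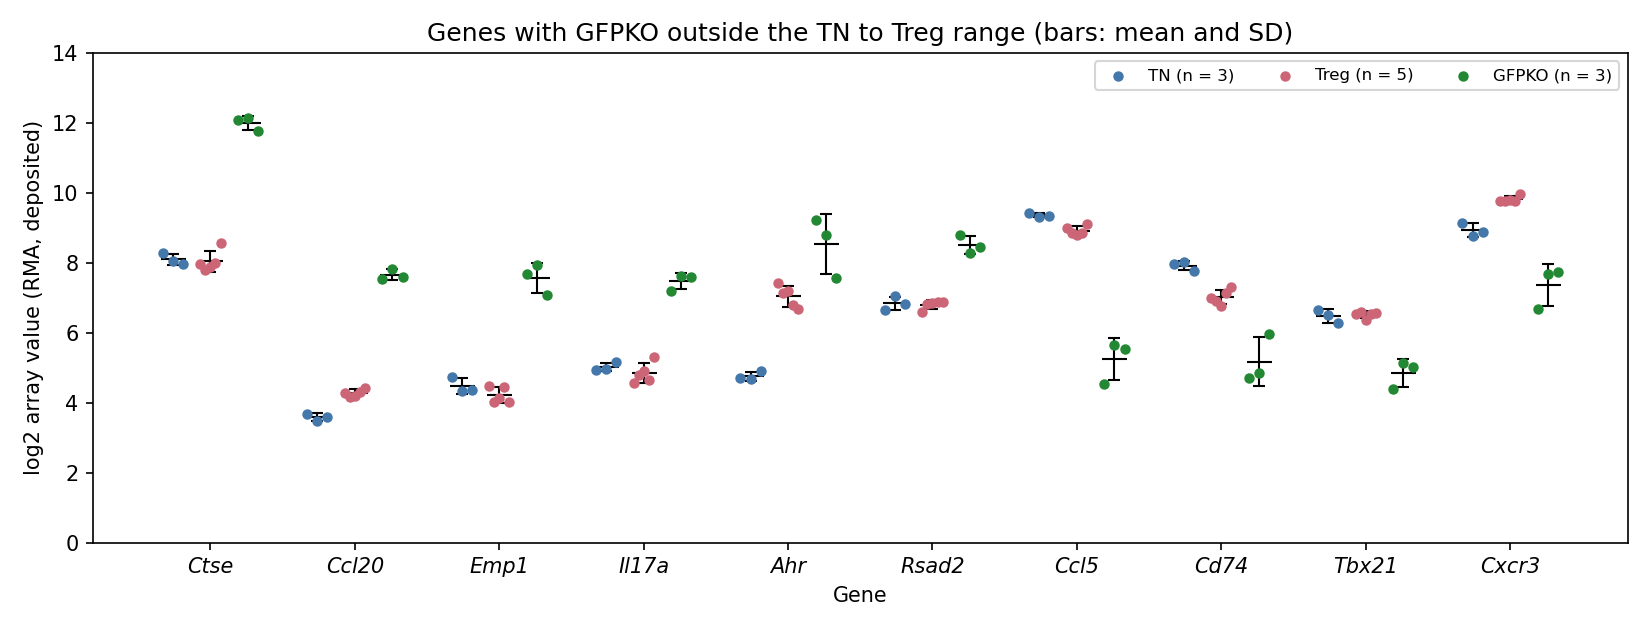
Deposited log2 values (y axis) of 10 genes with GFPKO outside the range of the other groups (x axis), per array of TN (n = 3), Treg (n = 5) and GFPKO (n = 3); bars are the mean and SD. Ctse, Ccl20, Emp1, Il17a, Ahr and Rsad2 are highest in GFPKO, and Ccl5, Cd74, Tbx21 and Cxcr3 lowest.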

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

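The tests of the Foxp3 pattern, and those of sex beyond the level of the sex-linked genes, were chosen only after the results were seen. The tests of a cell mixture and of other cell types were written before. For other cell types the reading rests on a different rule from the one written before.

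The Foxp3 probe set read at the TN level in the arrays labelled Treg (log2 fold change -0.0118) and higher in GFPKO. TN lay at background by definition, since that level was set at its highest Foxp3 value, and the Treg values lay below it (at most 3.64). That the difference in signal from GFPKO is a lower bound rests on this choice. It bounds the signal of the probe set only, not the difference in Foxp3 RNA, since the position of the probe set was not at hand. An exchange of the Treg and GFPKO labels is argued against by Eif2s3y, which is Y-linked and read at least 7.35 in every array labelled Treg, although heterozygous carriers of an X-linked gene are female. TN cells in the arrays labelled Treg are argued against by 27 of 28 Treg signature genes that read higher in each of these arrays than in any TN array. Whether the probe set reads a part of the transcript that differs between the alleles cannot be told apart from other causes, since there was 1 probe set and its position was not at hand. A difference in the amount of Foxp3 RNA between the null and the functional allele stays open as well and was not tested.

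Sex went with genotype in these arrays, as all GFPKO arrays showed the female pattern and all others the male one. The smallest gap between any GFPKO and any Treg array was 1.71 on the log2 scale over the sex-linked genes, seen in Uty, so for the genes that set GFPKO apart from Treg sex and genotype cannot be told apart. TN and Treg showed the same sex, so the changes that Treg minus GFPKO shares with Treg minus TN were examined. Without the sex-linked list their covariance was 0.0951, against at most 0.0104 in simulations of unchanged groups. The simulations held independent noise per gene and no sex effect. The covariance thus argues against sex as the whole cause only if sex does not move the same genes as Treg minus TN, which was not tested. For the genes with GFPKO outside the range of TN and Treg, 268 of which are not on the sex-linked list, sex and genotype cannot be told apart either.

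The Treg signature was lower in GFPKO than in Treg, with a median difference of 1.01 on the log2 scale. A mixture of Treg and TN cells in the GFPKO sort, taken alone, is argued against by the 26.4% of genes called in GFPKO minus TN that lay outside the range of TN and Treg (from 20.2% to 50.4% with 1 array left out, the highest without GFPKO replicate 3). Since these genes may partly follow sex or the technical differences of the GFPKO arrays, a mixture together with either stays open. For other cells in the GFPKO sort, neither outcome written beforehand was met. None of 26 B and myeloid markers was called higher in GFPKO than in both groups in limma (0 also at an unadjusted p under 0.05). The largest change over Treg was 0.16 in Blk. The B cell and myeloid medians were -0.43 and -0.11 against Treg and -0.34 and -0.24 against TN. Both B cell medians were farther from 0 than the bound set beforehand, but in the direction opposite to such cells. The medians against TN would also be low if the TN arrays held such cells, which was not tested. By the markers called and the largest change, a rule other than the one written, such cells are argued against for B and myeloid cells only. The lack of functional Foxp3 that the design names stays open as a biological explanation. It was not tested apart from sex, or from the actin and control probe differences of the GFPKO arrays.

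In 9 of the 157 named genes 1 Treg array stood apart from the other 4, where chance gives about 1 in 20, or 7.85. The measure is the gap to the nearest array divided by the whole range, with a critical value of 0.71. Treg replicate 5 stood apart in Ctse (8.56 against 7.79 to 8.00 in the others, ratio 0.731), Cxcr3 (9.97 against 9.76 to 9.80, 0.805), Il2ra (8.97 against 9.19 to 9.28, 0.721), Klrd1 (2.99 against 3.16 to 3.21, 0.763) and Lef1 (10.56 against 10.69 to 10.73, 0.783). Treg replicate 1 did so in Cxcr5 (8.70 against 8.45 to 8.51, 0.779) and Rsad2 (6.58 against 6.84 to 6.89, 0.817), Treg replicate 4 in Fas (8.07 against 8.25 to 8.31, 0.769) and Treg replicate 3 in Tbx21 (6.37 against 6.53 to 6.59, 0.754).

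Control probe sets that no comparison used were higher in each GFPKO array than in any other array. A difference in RNA input, RNA quality or array processing that went with GFPKO could not be told apart from genotype. The poly-A controls averaged 10.18 in GFPKO (9.69 to 11.02) against 9.03 to 9.45 in the TN arrays, a difference of 0.977 from the TN mean, and 8.64 to 9.35 in the Treg arrays. The hybridisation controls averaged 12.30 (11.89 to 12.85) against 11.06 to 11.73 in TN, a difference of 0.872 from the TN mean, and 10.95 to 11.71 in Treg.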

How the results depend on the processing

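No named gene or tested list that was called changed direction under the alternatives in which it was followed, but the balance of higher and lower genes did. Apart from Foxp3, named genes were not followed with each probe set by itself. Other probe sets of some called genes, such as Ighm, Btg2, Runx1 and Vipr1, had the opposite sign without being called. Counts are genes called for Treg minus TN, GFPKO minus TN and Treg minus GFPKO (1813, 1029 and 1716), the overlap of contrasts, that is genes called the same way in Treg and GFPKO against TN (632, here shared), and genes of GFPKO outside the TN to Treg range (272, here outside). Where a count moved by over 1.5 times, the cause was not tested unless the alternative itself is stricter or counts other units. The mean of probe sets, quantile normalization, median centring, the upper 60% of genes and the trended variance moved no count that far. Quantile normalization and median centring could change little, since RMA had already normalised the values by quantiles. With each probe set by itself the contrasts gave 3137, 1544 and 3991 probe sets, with 46.7% of the last higher in Treg against 73.0% of genes, and 444 outside the range. For GFPKO minus TN 46.6% were higher, against 59.8% with the actin covariate and 57.9% without TN replicate 1. Array weights (GFPKO replicate 2 at 5.11, replicates 1 and 3 at 0.254 and 0.307) gave 3223, 5051, 6756, 1517 shared and 2811 outside. Fits of only the groups compared gave 562 for GFPKO minus TN and 136 outside. Treg replicates 1 to 3 alone gave 929 for Treg minus GFPKO. At an adjusted p under 0.01 there were 586 for GFPKO minus TN, 832 for Treg minus GFPKO, 403 shared and 122 outside. At 2-fold or more there were 707, 437, 401, 297 and 69. Of the alternatives chosen after seeing the data, the actin covariate gave 570 for GFPKO minus TN, 811 for Treg minus GFPKO and 108 outside, and leaving out replicate 1 of all groups gave 165 outside. Of 60 list tests 22 were called with the estimated correlation, against 39. Of the 232 called combinations of named gene and contrast, 20 lost their call with the actin covariate, 14 with Treg replicates 1 to 3 alone, 11 without replicate 1 of all groups, 10 with the mean of probe sets, 10 in fits of only the groups compared, and at most 2 with array weights, quantile normalization, median centring, the trended variance or the upper 60%, where dim genes left out were not counted. Array weights and the upper 60% lost 3 of the 39 list calls each, and the mean of probe sets, the actin covariate, the fit without replicate 1 and fry 1 each.

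With 1 array left out the counts ranged from 1360 to 2398 for Treg minus TN, from 644 (without TN replicate 1) to 1868 (without GFPKO replicate 3) for GFPKO minus TN, from 1134 (without GFPKO replicate 1) to 3421 (without GFPKO replicate 3) for Treg minus GFPKO, from 448 to 736 shared, and from 163 (without TN replicate 1) to 941 (without GFPKO replicate 3) outside. The genes of GFPKO outside the TN to Treg range numbered 171 without TN replicate 2 and 178 without GFPKO replicate 2. Higher and lower counts ranged from 865 to 1464 and 388 to 934 for Treg minus TN, 355 to 644 and 271 to 1224 for GFPKO minus TN, and 782 to 2414 and 282 to 1007 for Treg minus GFPKO. Foxp3 in Treg minus GFPKO lay between -3.55 and -3.33, 217 to 229 of 232 called combinations of gene and contrast kept their call, and 37 to 40 list tests were called, with at most 2 of the 39 lost. In no fit was a group left with 1 array.

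A block for the replicate number, over replicates 1 to 3, gave 1436, 1028 and 1049 genes, and 12 named combinations and 2 list tests lost their call. Deviations of arrays with the same number correlated above 0.1 in 3 of 9 pairs (r from -0.22 to 0.51), so the numbers were not taken to pair the samples. The 3 pairs were those of replicate 1, whose arrays deviated together (0.21, 0.16 and 0.51). An array correlated best with its own number in 7 of 18 comparisons with another group. Arrays carry no detection calls, so signal over background was not tested. Dim genes such as the Y-linked ones in GFPKO lay among the lowest values.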

Other observations

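The genes higher in Treg than in TN fell into classes by where GFPKO lay. Of 1190 such genes, 205 were called in GFPKO minus TN the same way and not in Treg minus GFPKO, as was Coro2a, 492 were called in Treg minus GFPKO the same way and not in GFPKO minus TN, as was Klrg1, and 124 were called the same way in both, as was Itgae. In 333 neither call was made, 9 were called lower in GFPKO than in TN, and 27 were called higher in GFPKO than in Treg. Of the 623 genes lower in Treg, 229, 135 and 36 fell into these classes, with Tdrp and Sgk1 among the 36, while 206 had neither call, 6 were called higher in GFPKO than in TN and 11 were called lower in GFPKO than in Treg. The classes rest on thresholds, and the share in each moves with the counts of the contrasts.

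Other splits of the same arrays were fitted for each contrast. They treat arrays as separate samples, which the labels do not state, so they address chance between arrays only. Every other split mixes arrays of the groups compared, which widens the spread within groups and lowers its count. Chance is therefore not excluded by these counts. For Treg minus TN the real split gave 1813 genes and the highest of the others 0, so 1 of 56 splits gave as many, the smallest share possible. For Treg minus GFPKO it was 1716 genes against 0, again 1 of 56 splits. For GFPKO minus TN it was 1029 genes against 0, with 1 of 10 splits giving as many, and 10 splits are too few for a share under 0.05.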
